A study of Arabidopsis thaliana with 8 samples.

How the data were processed

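Gene expression in leaves of Arabidopsis thaliana (Col-0, 4 weeks old) was measured with 8 one-colour (Cy3) Agilent 8x60k arrays. Per the labels, leaves were infiltrated by syringe with DSF at 100 uM in methanol, and RNA was taken 4, 8 or 16 h later. A solvent control with methanol alone was taken at 16 h. DSF is the diffusible signal factor of Xanthomonas, a fatty acid that these bacteria use for signalling between cells. Each of the 4 groups had 2 arrays. The labels do not say whether the 2 arrays of a group came from separate plants, so p-values measure only the spread between these arrays, which may be technical. No methanol samples at 4 h or 8 h were analysed here.

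The deposited scanner files give an intensity per spot. Per the file headers, these signals were background-subtracted and detrended within each array by Agilent Feature Extraction 11.5.1.1, with no normalization between arrays, and the array design follows TAIR10. The authors also deposited processed values for 30487 loci in log2 units, called the authors' value table here. How these loci were made from probes is not given in the sources used here. Set against the scanner values, each of the 8 columns correlated best with its own array (r from 0.993 to 0.995 across loci, which are not independent replicates), lay higher by 0.37 to 0.43, and had a 75th percentile within 0.02 of 0. Their scale and centring therefore follow from the data, and the column medians were -2.69, -2.77, -2.77 and -2.72 for replicate 1 of DSF 4 h, DSF 8 h, DSF 16 h and methanol, and -2.73, -2.73, -2.77 and -2.83 for replicate 2. They served as an alternative only.

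From the scanner files, log2 of the processed signal minus each array's 75th percentile was taken for 56041 non-control spots. Outlier spots were left out and spots of one probe were averaged, which gave 40747 probes. A probe was tested if it was well above background on both arrays of at least 1 group. A gene with several probes took the probe with the highest mean over the 8 arrays. Of 29135 loci with a probe of their own, 28512 matched the reference gene table (assembly TAIR10.1, used only for names) and 10481 had a symbol. A further 1509 spots matched several loci or none and were not used. The fits covered 20281 genes, and 8854 loci with a probe were not tested. Signal, not read depth, sets the precision here. The 75th percentile of the signal was 1070 to 2180 per array, 70.3 to 73.9% of spots were well above background, and 0 spots were saturated. All arrays lay on 1 slide with 1 scan.

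Groups were compared with limma 3.58.1 (lmFit and eBayes, R 4.3.3) fitted to all 8 arrays, so that the groups shared one estimate of the spread. The 6 comparisons were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are given ± standard error, from 2 arrays per group. This is limma's moderated standard error, with the spread pooled over all 8 arrays. It therefore does not measure the spread of the 2 groups compared alone. The prior degrees of freedom were 2.79 and the total 6.79. The median 95% confidence interval of a log2 fold change extended 0.56 to either side. Where a gene was not well above background on any array of a group, the fold is a lower bound and is written as at least N-fold. It sets the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the gene's own signal. The bound holds for the processed signal only. Normexp, a background correction used as an alternative, adds an offset of 50 and gave smaller changes for several of these genes.

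There were 26 gene lists, 20 of pathways and 6 of markers for cell types or organs, with 373 of their 375 members on the array by a probe of their own. They were tested with camera at a preset correlation of 0.01, adjusted over all 156 tests. In all, 46 list tests passed, and with an estimated correlation 0 did (lowest adjusted p = 0.21 in camera). That estimate rests on only 8 arrays in 4 groups, so the test has little power here. Morning clock genes at 8 h over methanol also had 0.21, although 10 of 10 were lower, each at an unadjusted limma p under 0.05. Failing this test is therefore no evidence that a list was unchanged. The preset value, in turn, may be too low for genes that vary together. Named genes followed a rule. For each comparison with methanol it took the 8 highest and 8 lowest log2 fold changes among genes past the threshold with a symbol and arrays that do not overlap, and 5 and 5 for comparisons between DSF times. Where no gene passed it took the 4 smallest p-values among genes with a symbol. It added up to 4 members of each list by smallest p, or the 2 with the largest moderated t where none passed, and 14 defence, clock and photosynthesis genes at 16 h. Examples in the text are drawn from these. All 341 named results past the threshold had both arrays of one group above both of the other. The rule required this of the highest and lowest genes, so it is not support of its own. Groups, comparisons, lists, this rule and all alternatives were fixed before the data were examined. Ranges of a list's adjusted p over alternatives are with the preset correlation.

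The procedure was tested on simulated data. For DSF against methanol at 16 h, with 20276 genes in the step, it called 0.4% of genes changed by 0.5 on the log2 scale, 9.6% of those changed by 1, 84.2% of those changed by 2 and 95.2% of those changed by 3, and 6.2% of its calls were false. A list shifted by 0.5 was called in 20 of 20 draws, and unshifted lists in 10 of 500 tests. Simulated genes varied independently of each other, each with the same spread in all groups. The list counts therefore do not give the error rate for lists whose genes vary together. Alternatives changed the normalization, background correction, filter, outlier spots, probe summary, model, threshold and arrays included. Other software was Python 3.11.15, pandas 2.3.3, numpy 2.4.6, the R package data.table (version 1.17.8) and matplotlib 3.10.9.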

Results

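The series set out to profile early events of defence signalling by the DSF elicitor in Arabidopsis leaves. It held 2 arrays each of leaves at 4, 8 and 16 h after DSF infiltration and 2 arrays of methanol-infiltrated leaves at 16 h. Replicates correlated across genes at 0.98 in DSF 4 h, DSF 16 h and methanol and at 0.99 in DSF 8 h. Arrays of DSF 16 h correlated with those of methanol at 0.97 to 0.98, about as high as replicates. Replicate 1 of DSF 16 h correlated with methanol replicate 2 at 0.9822 and with its own replicate at 0.9817. The standard deviation of the difference between replicates was 0.58, 0.36, 0.56 and 0.56 for DSF 4 h, DSF 8 h, DSF 16 h and methanol. One DSF 16 h array, replicate 2, had the lowest 75th percentile of signal of the 8 arrays (1070) and a median of 8500 at the brightest spike-in control, where the other arrays had 26200 to 53000. The first principal component, with 42.3% of the variance, separated the arrays of 4 h and 8 h (-41.0 to -51.8) from those of 16 h (40.5 to 52.1), DSF and methanol alike. The component after it, with 20.2%, separated DSF 4 h (34.6 and 49.9) from DSF 8 h (-42.9 and -45.1). The next, with 14.7%, set methanol replicate 1 (-40.3, replicate 2 at -8.5) apart from replicate 2 of DSF 16 h (47.7, replicate 1 at 4.5) and of DSF 4 h (38.7, replicate 1 at -16.5).

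**Figure D1:**
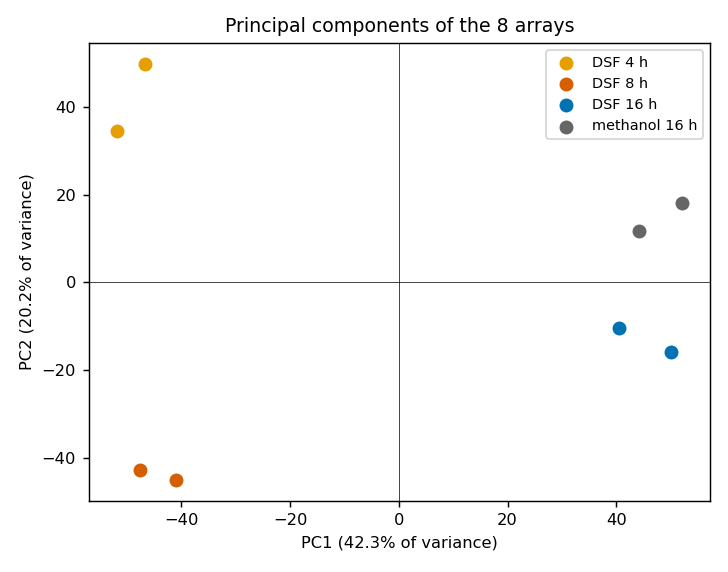
Principal component scores of the 8 arrays, with the first component (42.3% of variance) on the x axis and the second (20.2%) on the y axis, and each point 1 array coloured by group. The 4 arrays of 16 h lie at 40.5 to 52.1 on the first component, and the 4 earlier DSF arrays at -41.0 to -51.8.

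The comparison of DSF with methanol at 16 h asks how expression differed with DSF at a matched time. Genes of immunity, protein folding, detoxification and fatty acid breakdown lay slightly higher with DSF as groups, and none of the 4 lists passed without methanol replicate 1 or with an estimated correlation (adjusted p = 0.45 to 0.78 with an estimated correlation). No single gene passed the threshold. Among genes with a symbol, the smallest p-values belonged to 4 genes that were higher with DSF on both arrays. GRF7 (AT5G53660), a growth-regulating factor, was at least 3.08-fold higher (limma adjusted p = 0.098) and was not well above background on the methanol arrays. FHL (AT5G02200), a partner of the far-red receptor phytochrome A, had a log2 fold change of 2.11 ± 0.24. UKL2 (AT3G27190), a uridine kinase-like gene, had 1.40 ± 0.16, and MYB111 (AT5G49330), an activator of flavonol synthesis, had 1.28 ± 0.16 (adjusted p = 0.117). PR1 (AT2G14610) differed by 0.08 ± 0.39, PR2 (AT3G57260) by 0.15 ± 0.24 and PR5 (AT1G75040) by -0.15 ± 0.17, all genes that respond to salicylic acid. ICS1 (AT1G74710), which makes it, differed by 0.21 ± 0.29. FRK1 (AT2G19190, 0.73 ± 0.49) and WRKY33 (AT2G38470, 0.08 ± 0.20), which respond to microbial patterns, did not pass. Nor did PAD3 (AT3G26830, 0.94 ± 0.31), the last enzyme of camalexin synthesis, the defensin PDF1.2a (AT5G44420, -0.83 ± 0.41) and the jasmonate-responsive VSP2 (AT5G24770, -0.42 ± 0.28).

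Several gene lists shifted as groups without a member passing over all genes. Of 24 genes of pattern-triggered immunity, 19 were above 0, among them the bacterial elongation factor receptor EFR (AT5G20480, 0.66 ± 0.17) and the indole glucosinolate enzyme CYP81F2 (AT5G57220, 1.25 ± 0.33). Immunity genes had a median of 0.26 (camera adjusted p = 0.0041, adjusted p = 0.78 with an estimated correlation). Chaperones of the endoplasmic reticulum were above 0 in 10 of 11, with the disulfide isomerase PDIL1-1 (AT1G21750, 0.59 ± 0.23) and the unfolded protein response factor BZIP60 (AT1G42990, 0.51 ± 0.25). Chaperones had a median of 0.37 (camera adjusted p = 0.0084, adjusted p = 0.61 with an estimated correlation). In oxidative stress and detoxification, 17 of 21 were above 0, with the glutathione transferases GSTU1 (AT2G29490, 0.86 ± 0.24) and GSTU24 (AT1G17170, 0.79 ± 0.23). Oxidative stress genes had a median of 0.24 (camera adjusted p = 0.018, adjusted p = 0.71 with an estimated correlation). Peroxisomal beta-oxidation, which breaks down fatty acids, had 8 of 11 above 0. Beta-oxidation genes had a median of 0.25 (camera adjusted p = 0.025, adjusted p = 0.45 with an estimated correlation). Adjusted over the list alone, 2 beta-oxidation genes rose, the peroxisomal acyl-CoA synthetase LACS7 (AT5G27600, 0.87 ± 0.18) and the fatty acyl importer PXA1 (AT4G39850, 0.91 ± 0.20), and 0 did in the other 3 lists. At an unadjusted p under 0.05 the limma counts were 3 in pattern-triggered immunity, 1 in chaperones, 5 in oxidative stress and 4 in beta-oxidation. Over all genes the count was 2833 of 20281. That is a larger share than in immunity genes or chaperones, so their counts give no support to a shift. It is a smaller share than in oxidative stress or beta-oxidation.

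The other lists did not pass. Salicylic acid defence had 17 of 20 genes above 0, 0 of them past the threshold over all genes or adjusted over the list alone and 0 at an unadjusted limma p under 0.05. Salicylic acid genes had a median of 0.21 (camera adjusted p = 0.08, adjusted p = 0.71 with an estimated correlation). Adjusted over the list alone, the clock-regulated factor RVE1 (AT5G17300, -1.01 ± 0.23) fell among 10 morning clock genes and the auxin-responsive IAA5 (AT1G15580, -1.26 ± 0.17) among 13 genes of auxin and expansion growth. The core clock genes CCA1 (AT2G46830, -0.02 ± 0.19, other probes up to 0.54), LHY (AT1G01060, 0.70 ± 0.40), TOC1 (AT5G61380, 0.22 ± 0.26) and GI (AT1G22770, 0.38 ± 0.26) and the small subunit of Rubisco RBCS1A (AT1G67090, -0.13 ± 0.18, other probes -0.26 to 0.02) did not pass. The cysteine protease SAG12 (AT5G45890), a marker of late leaf senescence, had a large but uneven difference (4.66 ± 2.02, adjusted p = 0.365), with 1 of the 2 methanol arrays well above background. Among markers of other cell types and organs, the root glucosidase PYK10 (AT3G09260, -2.39 ± 0.87), the replication factor PCNA1 (AT1G07370, -0.90 ± 0.32), the xylem protease XCP1 (AT4G35350, -0.93 ± 0.33) and the wax gene CER1 (AT1G02205, -0.97 ± 0.37) had large moderated t in their lists and did not pass. None of the 6 marker lists passed camera in any of the 6 comparisons (lowest adjusted p = 0.086 with the preset correlation and adjusted p = 0.56 with an estimated correlation). Median, mean and test differed in sign for ethylene and defensins, darkness and sugar starvation, guard cells, root and flower.

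With limma, 0 of 20281 genes passed, and 2833 had an unadjusted p under 0.05, where 1014 would be so by chance. Groups did not overlap for 43.5% of genes, against 33.3% by chance. Quantile normalization called 2 genes, GRF7 and AT3G44005, a locus without a symbol that was chosen after its values were seen (3.14 ± 0.30, adjusted p = 0.12 in limma with the percentile scaling, and not well above background on the methanol arrays). Each other alternative called 0, with 1662 to 4095 genes at an unadjusted p under 0.05. The number of lists that passed was 4 with all arrays, 1 without methanol replicate 1 (touch, wound and cold, none of the 4), 2 without DSF 16 h replicate 1 and 8 without methanol replicate 2. With fry, a test of whether the genes of a list move one way on balance, it was 1. Immunity genes no longer passed without DSF 16 h replicate 1 (adjusted p = 0.1) and without methanol replicate 1 (adjusted p = 0.078), with a range over alternatives of 0.0011 to 0.1. Oxidative stress genes no longer passed without DSF 16 h replicate 1 (median 0.15, adjusted p = 0.23) and without methanol replicate 1 (adjusted p = 0.27), with a range over alternatives of 0.0021 to 0.27. Their median was 0.38 with the mean of all probes and 0.50 without DSF 16 h replicate 2. Chaperones no longer passed without methanol replicate 1 (median 0.25, adjusted p = 0.12) and without DSF 16 h replicate 2 (adjusted p = 0.074), with a range over alternatives of 0.00045 to 0.12. Beta-oxidation genes no longer passed without methanol replicate 1 (median 0.17, adjusted p = 0.13) and without DSF 16 h replicate 2 (median 0.11, adjusted p = 0.085), with a range over alternatives of 0.0053 to 0.13. Their median was 0.39 without DSF 16 h replicate 1.

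**Figure D2:**
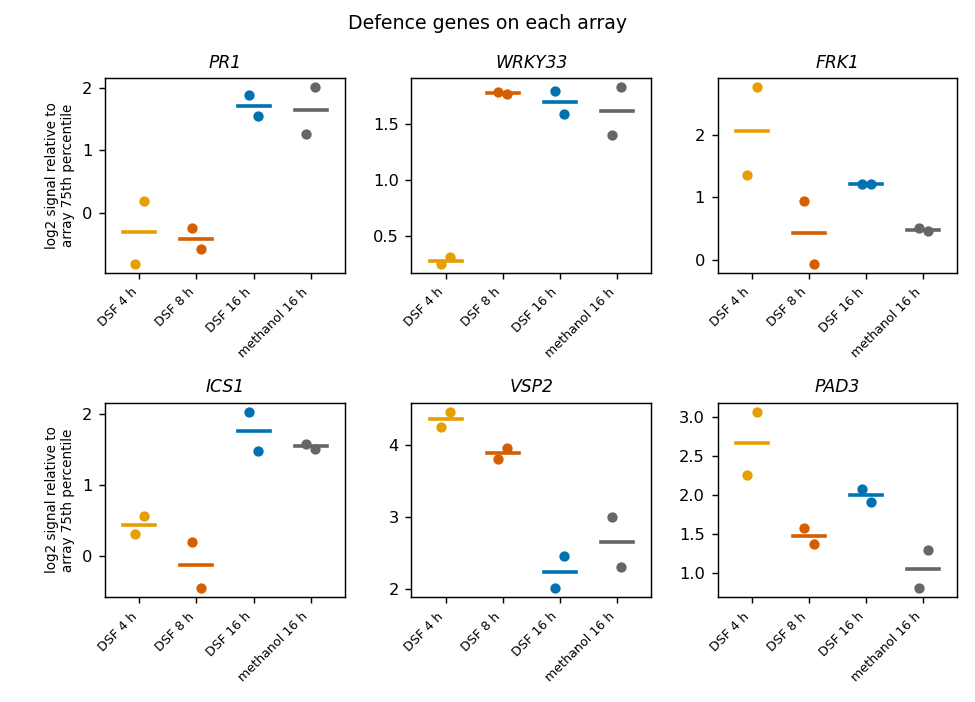
Log2 signal relative to each array's 75th percentile for 6 defence genes, with each point 1 array and each bar the mean of a group's 2 arrays. At 16 h the log2 fold change of DSF over methanol was 0.08 for PR1, 0.08 for WRKY33, 0.73 for FRK1, 0.21 for ICS1, -0.42 for VSP2 and 0.94 for PAD3, none past the threshold.

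DSF at 4 h was set against the only methanol group, that of 16 h, so time after infiltration and time of day differed along with treatment. The comparison asks which genes stood apart early after DSF. Morning clock genes and chaperones of the endoplasmic reticulum were lower as groups, and evening clock, heat shock and jasmonate genes were higher (adjusted p = 0.21 to 0.71 with an estimated correlation). COR27 (AT5G42900), a regulator that links cold and the clock, rose by 6.51 ± 0.25 on the log2 scale (limma adjusted p = 0.000392). The glutathione transferase GSTU25 (AT1G17180) rose by 5.61 ± 0.50, the clock-linked histone demethylase JMJD5 (AT3G20810) by 5.28 ± 0.52, the MYB factor RVE2 (AT5G37260) by 4.63 ± 0.33, the cytochrome P450 CYP81F4 (AT4G37410) by 4.56 ± 0.50 and the evening gene ELF4 (AT2G40080) by 4.52 ± 0.23. The flavonol arabinosyltransferase UGT78D3 (AT5G17030) was at least 9.12-fold higher and the cytochrome P450 CYP96A5 (AT2G21910) at least 9.99-fold higher, neither being well above background with methanol. At the other end, DREB26 (AT1G21910, -5.50 ± 0.43), ESE3 (AT5G25190, -4.79 ± 0.26) and bZIP3 (AT5G15830, -3.83 ± 0.26), all transcription factors, the beta-xylosidase BXL1 (AT5G49360, -4.48 ± 0.45), the CONSTANS-like COL2 (AT3G02380, -4.12 ± 0.29), the brassinosteroid-responsive EXO (AT4G08950, -4.05 ± 0.53) and the homeodomain factor HAT1 (AT4G17460, -3.98 ± 0.45) fell. BZIP61 (AT3G58120, -3.85 ± 0.47) also fell, with 1 of its 2 DSF arrays well above background.

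In the clock, 7 of 10 morning genes fell, and 9 fell adjusted over the list alone, led by CCA1 (-3.80 ± 0.19), LNK2 (AT3G54500, -2.23 ± 0.17), LNK3 (AT3G12320, -2.21 ± 0.19) and RVE1 (-2.30 ± 0.23). Morning genes had a median of -2.26 (camera adjusted p = 3.8e-09, adjusted p = 0.21 with an estimated correlation). Of 11 evening genes, 8 rose and 1 fell, with the same counts adjusted over the list alone, led by BOA (AT5G59570, 4.05 ± 0.16), ELF4, PRR3 (AT5G60100, 3.32 ± 0.19) and the blue-light receptor FKF1 (AT1G68050, 2.66 ± 0.22). Evening genes had a median of 2.12 (camera adjusted p = 9.7e-07, adjusted p = 0.21 with an estimated correlation). Heat shock genes rose in 7 of 11, and 8 adjusted over the list alone. Heat shock genes had a median of 1.37 (camera adjusted p = 0.00025, adjusted p = 0.39 with an estimated correlation). They included the chaperones HSP90.1 (AT5G52640, 3.25 ± 0.20), which had -0.75 in the authors' value table, and HSP70 (AT3G12580, 2.68 ± 0.19), and HSP23.6 (AT4G25200) at least 5.39-fold. Chaperones of the endoplasmic reticulum fell in 2 of 11, BIP3 (AT1G09080, -2.81 ± 0.45) and SDF2 (AT2G25110, -0.86 ± 0.18), and 7 adjusted over the list alone. Chaperones had a median of -0.56 (camera adjusted p = 0.00018, adjusted p = 0.51 with an estimated correlation).

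Jasmonate genes rose in 7 of 22, and 11 adjusted over the list alone, among them the storage proteins VSP1 (AT5G24780, 2.71 ± 0.36) and VSP2 (1.72 ± 0.28), the methyl jasmonate enzyme JMT (AT1G19640, 1.73 ± 0.27) and the master regulator MYC2 (AT1G32640, 1.49 ± 0.28). Jasmonate genes had a median of 1.04 (camera adjusted p = 6.7e-05, adjusted p = 0.71 with an estimated correlation). In oxidative stress and detoxification, 7 rose and 1 fell of 21, and 8 and 2 adjusted over the list alone, with GSTU24 (2.77 ± 0.23), GSTU25, GSTU1 (2.12 ± 0.24) and the auxin glucosyltransferase UGT74E2 (AT1G05680, 3.57 ± 0.35). Oxidative stress genes had a median of 0.84 (camera adjusted p = 0.0045, adjusted p = 0.61 with an estimated correlation). Of 22 phenylpropanoid and flavonoid genes the flavonol synthase FLS1 (AT5G08640, 1.93 ± 0.25) and the anthocyanin activator MYB75 (AT1G56650, 1.23 ± 0.26) rose, the phenylalanine lyase PAL4 (AT3G10340, -0.95 ± 0.22) fell, and 7 rose and 1 fell adjusted over the list alone. Phenylpropanoid genes had a median of 0.66 (camera adjusted p = 0.0084, adjusted p = 0.71 with an estimated correlation). Photosynthesis genes fell in 3 of 29, the same count as adjusted over the list alone, namely plastocyanin PETE1 (AT1G76100, -1.28 ± 0.24) and the light-harvesting genes LHCB2.1 (AT2G05100, -1.57 ± 0.30) and LHCB2.2 (AT2G05070, -1.68 ± 0.39). Photosynthesis genes had a median of -0.18 (camera adjusted p = 0.0048, adjusted p = 0.9 with an estimated correlation). Of 12 genes of darkness and sugar starvation, 4 fell, TPS8 (AT1G70290, -2.61 ± 0.28), TPS11 (AT2G18700, -2.34 ± 0.25), DIN10 (AT5G20250, -1.69 ± 0.19) and SEN1 (AT4G35770, -2.37 ± 0.51), while 1 rose, with 7 and 2 adjusted over the list alone. Starvation genes had a median of -0.60 (camera adjusted p = 0.02, adjusted p = 0.43 with an estimated correlation).

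The lists of salicylic acid defence, pattern-triggered immunity, camalexin, other WRKY factors and ethylene did not pass camera. Of 20 genes of salicylic acid defence, 2 rose and 4 fell (2 and 5 adjusted over the list alone), with PR1 (-1.96 ± 0.39) and PR5 (-0.91 ± 0.17) lower and the repressor WRKY38 (AT5G22570, 1.51 ± 0.31) higher. SAG101 (AT5G14930) fell by 0.93 with 1 of its 3 probes at 0.15. Of 24 pattern-triggered immunity genes, 4 rose, such as the ubiquitin ligase PUB22 (AT3G52450, 2.48 ± 0.30) and EFR (1.05 ± 0.17), and 3 fell, such as WRKY33 (-1.34 ± 0.20) and the kinase MPK3 (AT3G45640, -1.04 ± 0.19) (7 and 3 adjusted over the list alone). The camalexin enzyme PAD3 (1.60 ± 0.31) and the glucosinolate regulator MYB34 (AT5G60890, 1.75 ± 0.25) rose and MYB51 (AT1G18570, -1.29 ± 0.25) fell, 3 of 16 in that list (2 higher and 2 lower adjusted over the list alone). WRKY54 (AT2G40750, 1.61 ± 0.21) was the 1 of 13 other WRKY factors to rise, over all genes and adjusted over the list alone. The ethylene response factors ERF6 (AT4G17490, -2.34 ± 0.23) and ERF104 (AT5G61600, -1.19 ± 0.24) fell, and 2 of 19 rose and 3 fell adjusted over the list alone. The touch-responsive TCH4 (AT5G57560, -3.55 ± 0.31) and TCH3 (AT2G41100, -0.88 ± 0.17) fell and the cold regulator CBF3 (AT4G25480, 2.78 ± 0.40) rose (3 and 3 adjusted over the list alone). The abscisic acid hydroxylase CYP707A3 (AT5G45340, -2.94 ± 0.22) fell, while the cold-regulated COR15B (AT2G42530, 1.31 ± 0.23) and COR15A (AT2G42540, 1.15 ± 0.23) rose (1 and 4 adjusted over the list alone). Among markers, the sucrose exporter SWEET12 (AT5G23660, 0.83 ± 0.21) and the nitrate transporter NRT2.1 (AT1G08090, 1.53 ± 0.28) rose. Median, mean and test differed in sign for ethylene and defensins, beta-oxidation, guard cells and vascular tissue.

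In all, 1341 genes were higher and 976 lower in DSF 4 h than in methanol 16 h (limma, 2317 of 20281 past the threshold). Without 1 array the count was 1186 (DSF 4 h replicate 1), 722 (DSF 4 h replicate 2, 352 higher and 370 lower), 1209 (either DSF 8 h array), 916 (methanol replicate 1) or 1127 (methanol replicate 2). Phenylpropanoid genes no longer passed without DSF 4 h replicate 2 (median 0.30, adjusted p = 0.13) and without methanol replicate 2 (adjusted p = 0.064), with a range over alternatives of 0.00022 to 0.13. Their median was 0.99 without DSF 4 h replicate 1. Oxidative stress genes no longer passed without DSF 4 h replicate 2 (median 0.33, adjusted p = 0.068), with a range over alternatives of 0.00023 to 0.068. Their median was 0.42 with normexp. Photosynthesis genes no longer passed with quantile normalization (median -0.05, adjusted p = 0.22) and without DSF 4 h replicate 1 (median -0.06, adjusted p = 0.32), with a range over alternatives of 3.1e-05 to 0.32. Their median was -0.32 with the mean of all probes and -0.37 without DSF 4 h replicate 2. Starvation genes no longer passed with the mean of all probes (adjusted p = 0.057) and without methanol replicate 2 (adjusted p = 0.072), with a range over alternatives of 0.0072 to 0.072. Their median was -0.36 without DSF 4 h replicate 2. The median of jasmonate genes was 0.64 without DSF 4 h replicate 2. In the authors' value table CCA1 was -1.38, and ERF6 (-0.77, adjusted p = 0.752), DIN10 (-1.07, adjusted p = 0.344) and SAG101 (-0.57, adjusted p = 0.108) did not pass, nor did SAG101 with the mean of all probes (-0.56, adjusted p = 0.106). With normexp CYP81F4 was 2.94, BZIP61 -1.53 and bZIP3 -2.22, and HSP23.6 did not pass (0.808, limma adjusted p = 0.0771). UGT78D3 was 1.215 and CYP96A5 1.297 with normexp on the log2 scale. UGT78D3, CYP96A5 and HSP23.6 were thus smaller in size than their bounds.

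**Figure D3:**
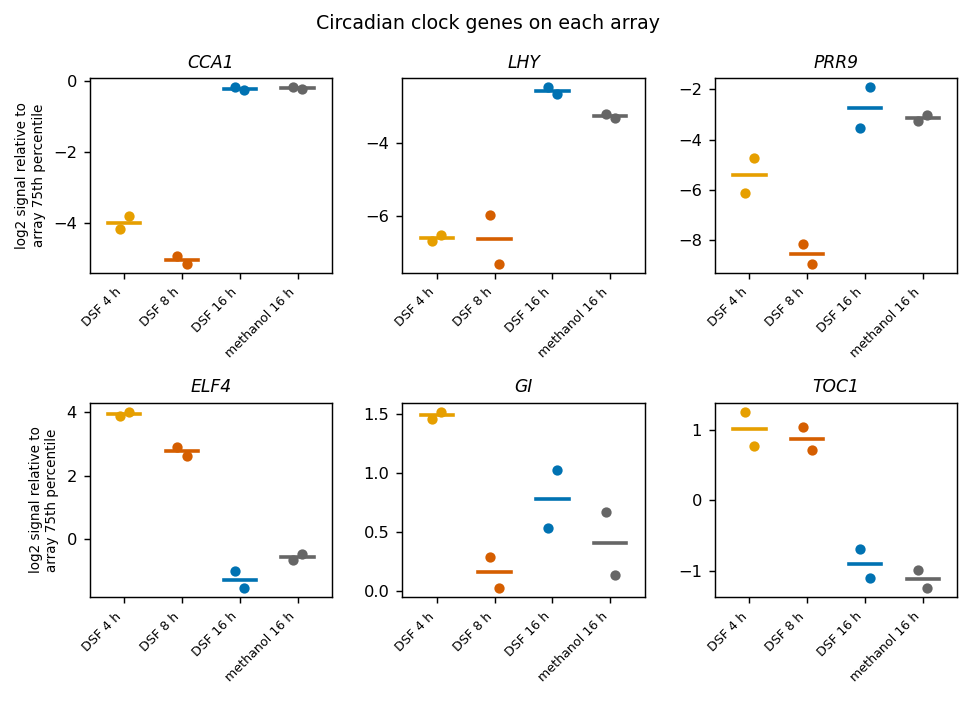
Log2 signal relative to each array's 75th percentile for 6 circadian clock genes, with each point 1 array and each bar the mean of a group's 2 arrays. CCA1 had log2 fold changes over methanol at 16 h of -3.80 at 4 h, -4.86 at 8 h and -0.02 at 16 h, and ELF4 was higher by 4.52 at 4 h and 3.34 at 8 h.

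At 8 h, DSF was again set against methanol at 16 h, which asks what stood apart at the middle time. Photosynthesis, auxin and morning clock genes were lower as groups, and phenylpropanoid and jasmonate genes were higher (adjusted p = 0.21 to 0.61 with an estimated correlation). The kinase gene CIPK20 (AT5G45820) was at least 511-fold lower, the seed dormancy gene DOG1 (AT5G45830) at least 18.6-fold lower and the morning clock gene PRR9 (AT2G46790) at least 22.3-fold lower, none well above background with DSF. The light-harvesting genes LHCB2.1 (-5.90 ± 0.30), LHCB2.2 (-5.88 ± 0.39) and LHCB2.3 (AT3G27690, -5.44 ± 0.35) and the B-box factor BBX28 (AT4G27310, -5.73 ± 0.37) fell. PORA (AT5G54190, -6.62 ± 0.85), a chlorophyll synthesis enzyme, fell with 1 of its 2 DSF arrays well above background. CYP81F4 rose by 6.37 ± 0.50, JMJD5 by 6.33 ± 0.52, RVE2 by 5.29 ± 0.33 and COR27 by 5.03 ± 0.25, as did the flavonoid regulator TT8 (AT4G09820, 4.75 ± 0.36) and flavonoid hydroxylase F3'H (AT5G07990, 4.58 ± 0.64). The flowering regulator CO (AT5G15840) was at least 16.7-fold and UGT78D3 at least 7.74-fold higher.

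All 10 morning clock genes fell, over all genes and adjusted over the list alone, with CCA1 (-4.86 ± 0.19), LNK3 (-4.13 ± 0.19), LNK2 (-3.26 ± 0.17) and PRR7 (AT5G02810, -2.26 ± 0.22). Morning genes had a median of -2.76 (camera adjusted p = 2e-11, adjusted p = 0.21 with an estimated correlation). Evening genes were split, 4 higher and 2 lower of 11 with the same counts adjusted over the list alone, for example BOA (4.45 ± 0.16) and PRR5 (AT5G24470, -1.94 ± 0.16), and did not pass. Photosynthesis genes fell in 9 of 29, and 11 adjusted over the list alone, including LHCB1.1 (AT1G29920, -4.02 ± 0.19) and LHCB3 (AT5G54270, -2.78 ± 0.22). Photosynthesis genes had a median of -0.43 (camera adjusted p = 3.6e-08, adjusted p = 0.61 with an estimated correlation). Phenylpropanoid and flavonoid genes rose in 12 of 22 and fell in 1, and 14 and 1 adjusted over the list alone. Phenylpropanoid genes had a median of 1.95 (camera adjusted p = 5e-07, adjusted p = 0.49 with an estimated correlation). They included FLS1 (3.29 ± 0.25), chalcone isomerase CHI (AT3G55120, 3.20 ± 0.31), the phenylalanine lyase PAL2 (AT3G53260, 2.19 ± 0.22) and the coumarate ligase 4CL3 (AT1G65060, 4.31 ± 0.44). Auxin and expansion growth genes fell in 7 of 13, and 8 adjusted over the list alone, with the auxin-responsive IAA19 (AT3G15540, -1.53 ± 0.24) and the expansins EXPA8 (AT2G40610, -2.68 ± 0.47) and EXPA11 (AT1G20190, -2.28 ± 0.40). Auxin genes had a median of -0.85 (camera adjusted p = 8.4e-05, adjusted p = 0.49 with an estimated correlation). In darkness and sugar starvation 4 of 12 fell and 1 rose, 6 and 2 adjusted over the list alone, with asparagine synthetase ASN1 (AT3G47340, -3.32 ± 0.51) and SEN1 (-2.88 ± 0.51) lower. Starvation genes had a median of -0.60 (camera adjusted p = 0.018, adjusted p = 0.43 with an estimated correlation).

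On the defence side, jasmonate genes rose in 5 of 22, and 15 adjusted over the list alone, with VSP1 (2.32 ± 0.36), JMT (1.63 ± 0.27), VSP2 (1.24 ± 0.28) and the repressor JAZ5 (AT1G17380, 1.68 ± 0.38). Jasmonate genes had a median of 1.18 (camera adjusted p = 6.2e-07, adjusted p = 0.61 with an estimated correlation). Of 24 pattern-triggered immunity genes 3 rose, the same count as adjusted over the list alone, EFR (1.05 ± 0.17), PUB22 (1.68 ± 0.30) and the NADPH oxidase RBOHD (AT5G47910, 0.87 ± 0.20). Immunity genes had a median of 0.33 (camera adjusted p = 0.039, adjusted p = 0.9 with an estimated correlation). Other WRKY factors rose in 5 of 13 (5 higher and 1 lower adjusted over the list alone), with WRKY54 (2.32 ± 0.21), WRKY60 (AT2G25000, 1.21 ± 0.22), WRKY18 (AT4G31800, 1.45 ± 0.27) and WRKY51 (AT5G64810, 1.34 ± 0.27). WRKY factors had a median of 0.76 (camera adjusted p = 0.039, adjusted p = 0.87 with an estimated correlation). Salicylic acid defence did not pass as a list. There, 5 of 20 genes fell, such as PR5 (-1.84 ± 0.17), the pipecolic acid enzyme ALD1 (AT2G13810, -2.21 ± 0.34) and ICS1 (-1.68 ± 0.29), and 2 rose, such as WRKY38 (2.13 ± 0.31) (8 and 5 adjusted over the list alone). The cold regulators CBF2 (AT4G25470, -3.85 ± 0.36), CBF3 (-3.35 ± 0.40) and CBF1 (AT4G25490, -2.50 ± 0.42) fell (1 higher and 3 lower adjusted over the list alone). In beta-oxidation the thiolase KAT5 (AT5G48880, 1.52 ± 0.24) and the synthetases LACS7 (0.92 ± 0.18) and LACS6 (AT3G05970, 0.88 ± 0.19) rose and ACX4 (AT3G51840, -1.31 ± 0.17) fell, the same counts as adjusted over the list alone. ERF6 (-1.30 ± 0.23) fell and had 0.29 in the authors' value table. Among markers, SWEET12 (1.55 ± 0.21) and NRT2.1 (1.75 ± 0.28) rose, and XCP1 (-2.11 ± 0.33) and the guard cell gene GC1 (AT1G22690, -1.04 ± 0.24) fell. Median, mean and test differed in sign for leaf senescence and abscisic acid.

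In total, 1164 genes were higher and 1043 lower (limma, 2207 past the threshold), and the count was 274 and 388 without DSF 8 h replicates 1 and 2 and 911 and 1161 without methanol replicates 1 and 2. The balance turned to 110 higher and 164 lower and to 169 higher and 219 lower without DSF 8 h replicates 1 and 2, and to 559 higher and 602 lower without methanol replicate 2. Immunity genes no longer passed without DSF 8 h replicate 1 (adjusted p = 0.18), without DSF 16 h replicate 1 (adjusted p = 0.052) and without methanol replicate 1 (adjusted p = 0.19), with a range over alternatives of 0.0087 to 0.19. WRKY factors no longer passed with the replicate block (adjusted p = 0.055), without DSF 8 h replicate 1 (median 0.40, adjusted p = 0.1), without DSF 16 h replicate 1 (adjusted p = 0.07), without methanol replicate 1 (median 0.19, adjusted p = 0.16) and without DSF 16 h replicate 2 (adjusted p = 0.063), with a range over alternatives of 0.0096 to 0.16. Their median was 1.3 without methanol replicate 2. Starvation genes no longer passed without methanol replicate 2 (adjusted p = 0.07), with a range over alternatives of 0.0068 to 0.07. The median of photosynthesis genes was -0.19 with quantile normalization and -1.16 with the mean of all probes. Lower genes also outnumbered higher ones with normexp (946 and 935) and without a filter on dim probes (539 and 507). In the authors' value table CCA1 was -2.42, and PRR7 (-0.32, adjusted p = 0.888), 4CL3 (1.44, adjusted p = 0.11), ASN1 (-1.07, adjusted p = 0.349) and EXPA8 (-1.24, adjusted p = 0.154) did not pass. With normexp PORA was -2.99 and CBF1 -1.59, and with normexp and quantile normalization ALD1 was -1.45. CIPK20 was -6.11, DOG1 -1.93, PRR9 -2.01, CO 1.8 and UGT78D3 1.08 with normexp on the log2 scale, smaller in size than their bounds.

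**Figure D4:**
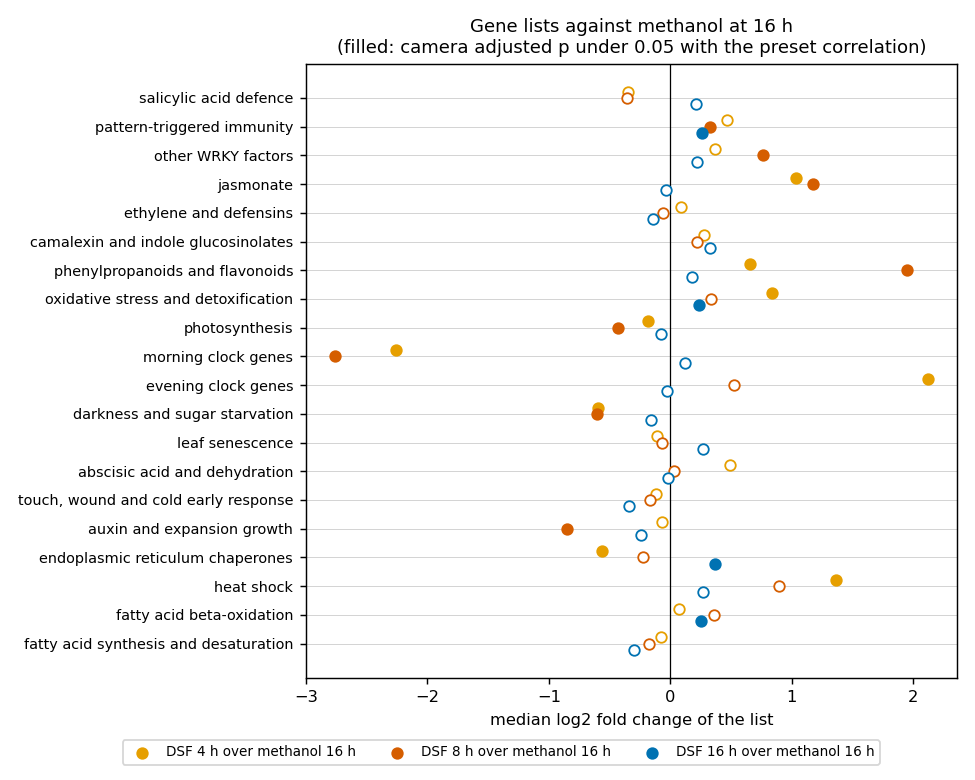
Median log2 fold change of 20 pathway lists in DSF at 4, 8 and 16 h over methanol at 16 h, with filled points past an adjusted p of 0.05 in camera with the preset correlation. Morning clock genes lie at -2.26 and -2.76 at 4 and 8 h and at 0.12 at 16 h, and jasmonate genes at 1.04, 1.18 and -0.03.

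The 4 h and 8 h results shared many genes, with 538 higher and 473 lower in both, BOA and COR27 being higher and CCA1 and LNK2 lower in both, and 14 in opposite directions. Independent lists of these sizes would share 77 and 50.2. Unchanged groups simulated against the same 2 methanol arrays shared 0, a count that is near 0 whenever no gene differs and so sets no level for these. Fold changes correlated across genes at 0.67 (0.50 simulated), with a covariance of 0.402 against 0.051 simulated, a difference of 0.351. With 1 methanol array for the 4 h effect and the other for the 8 h effect, so that no array was shared, the covariance was 0.324 with either assignment. The counts were not repeated this way, as 1 control array is left on each side, so part of their excess may come from the shared controls. The shared count of 1011 was 648 and 419 without DSF 4 h replicates 1 and 2, 182 and 225 without DSF 8 h replicates 1 and 2, and 384 and 487 without methanol replicates 1 and 2. The 16 h effect had a covariance of 0.109 with that at 4 h (0.051 simulated) and 0.154 with that at 8 h (0.052 simulated), at correlations of 0.29 and 0.40 (0.50 simulated for both). With the methanol arrays split in the same way it was 0.043 and 0.019 for 4 h and 0.088 and 0.064 for 8 h.

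Early differences were also set against DSF at 16 h, with the early arrays shared by both comparisons. Of the 2317 genes called at 4 h against methanol, 1599 (69%) were called in the same direction against DSF at 16 h. At 8 h this held for 1167 of 2207 (52.9%). Across genes the fold changes correlated at 0.80 at 4 h and 0.79 at 8 h, and at 0.50 in unchanged groups simulated with the early arrays shared. With 1 early array set against methanol and the other against DSF at 16 h, so that no array was shared, the covariance of fold changes across genes was 0.443 and 0.356 at 4 h and 0.424 and 0.427 at 8 h. The splits here and for methanol were chosen after the counts were seen. Among the called genes the median change at 4 h was 1.3 against methanol and 1.16 against DSF 16 h, and in the same direction DSF over methanol at 16 h was 0.17. At 8 h the medians were 1.38, 1.07 and 0.34. COR27, for example, was 6.51 at 4 h over methanol, and DSF at 16 h differed from DSF at 4 h by -6.70.

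Comparing 8 h with 4 h asks how expression moved early in the DSF series, with no methanol arrays of these times beside it. Photosynthesis and heat shock genes were lower at 8 h as groups, and phenylpropanoid genes were higher (adjusted p = 0.25 to 0.71 with an estimated correlation). CIPK20 was at least 71.4-fold lower at 8 h and the ethylene response factor ERF71 (AT2G47520) at least 7.61-fold lower. CBF3 (-6.13 ± 0.40), the galactinol synthase GolS3 (AT1G09350, -4.85 ± 0.26) and GSTU25 (-4.58 ± 0.50) fell. DREB26 (5.15 ± 0.43), the lipid transfer protein LTP6 (AT3G08770, 4.02 ± 0.51), F3'H (3.91 ± 0.64) and EXO (3.84 ± 0.53) rose, and the florigen gene FT (AT1G65480) was at least 7.62-fold higher.

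Phenylpropanoid and flavonoid genes rose in 9 of 22, and 11 adjusted over the list alone, with PAL2 (1.82 ± 0.22), F3H (AT3G51240, 3.35 ± 0.41) and LDOX (AT4G22880, 3.38 ± 0.52), and with 4CL3 (2.85 ± 0.44), which had -0.01 in the authors' value table. Phenylpropanoid genes had a median of 0.88 (camera adjusted p = 0.0001, adjusted p = 0.61 with an estimated correlation). Heat shock genes fell in 5 of 11, and 6 adjusted over the list alone, including the co-chaperone ROF2 (AT5G48570, -2.61 ± 0.25) and HSP90.1 (-1.98 ± 0.20). Heat shock genes had a median of -1.42 (camera adjusted p = 1.1e-05, adjusted p = 0.25 with an estimated correlation). Photosynthesis genes fell in 5 of 29, and 7 adjusted over the list alone, with LHCB1.1 (-3.38 ± 0.19) and LHCB2.1 (-4.33 ± 0.30). Photosynthesis genes had a median of -0.23 (camera adjusted p = 1.6e-05, adjusted p = 0.71 with an estimated correlation). Evening clock genes fell in 5 of 11, and 7 adjusted over the list alone, led by PRR5 (-2.77 ± 0.16) and FKF1 (-2.14 ± 0.22). Evening genes had a median of -0.76 (camera adjusted p = 7.3e-05, adjusted p = 0.21 with an estimated correlation). Among morning genes 4 fell and 1 rose of 10, and 6 and 2 adjusted over the list alone, with LNK3 (-1.91 ± 0.19) lower, PRR7 (-1.59 ± 0.22) lower but at 0.37 in the authors' value table, and RVE1 (1.38 ± 0.23) higher. Morning genes had a median of -1.04 (camera adjusted p = 0.008, adjusted p = 0.51 with an estimated correlation).

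Auxin and growth genes fell in 3 of 13, and 7 adjusted over the list alone, with IAA19 (-1.94 ± 0.24) and EXPA1 (AT1G69530, -1.57 ± 0.26). Auxin genes had a median of -1.32 (camera adjusted p = 0.00018, adjusted p = 0.51 with an estimated correlation). Oxidative stress genes fell in 4 of 21, and 9 adjusted over the list alone, including UGT74E2 (-3.23 ± 0.35) and superoxide dismutase CSD1 (AT1G08830, -1.55 ± 0.22). Oxidative stress genes had a median of -0.49 (camera adjusted p = 0.00089, adjusted p = 0.61 with an estimated correlation). In abscisic acid and dehydration CYP707A3 rose (adjusted p = 0.00867) and COR15B (-1.41 ± 0.23) fell, with 1 and 5 adjusted over the list alone. Abscisic acid genes had a median of -0.30 (camera adjusted p = 0.031, adjusted p = 0.9 with an estimated correlation). Chaperones of the endoplasmic reticulum passed as a list with 0 limma calls over all genes or adjusted over the list alone and 1 at an unadjusted p under 0.05, SDF2 (0.50 ± 0.18). Chaperones had a median of 0.37 (camera adjusted p = 0.0092, adjusted p = 0.61 with an estimated correlation). WRKY33 (1.50 ± 0.20) and MPK3 (1.08 ± 0.19) rose, 2 of 24 pattern-triggered immunity genes (5 higher and 2 lower adjusted over the list alone). PR5 (-0.93 ± 0.17), ALD1 (-1.77 ± 0.34) and the pipecolic acid enzyme FMO1 (AT1G19250, -1.65 ± 0.30) fell, 3 of 20 in salicylic acid defence (2 higher and 3 lower adjusted over the list alone). Median, mean and test differed in sign for salicylic acid defence, pattern-triggered immunity, ethylene and defensins, sugar starvation, and touch, wound and cold.

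Altogether 385 genes were higher and 401 lower at 8 h (limma, 786 past the threshold), with 151 and 154 (81 higher and 73 lower) without DSF 4 h replicates 1 and 2 and 13 and 26 without DSF 8 h replicates 1 and 2. Oxidative stress genes no longer passed without DSF 4 h replicate 2 (median -0.14, adjusted p = 0.068), with a range over alternatives of 1.4e-05 to 0.068. Their median was -0.32 with normexp, -0.81 with the mean of all probes, -1.0 without DSF 4 h replicate 1 and -0.19 without DSF 8 h replicate 1. Abscisic acid genes no longer passed without DSF 8 h replicate 1 (adjusted p = 0.078) and without DSF 4 h replicate 2 (median -0.12, adjusted p = 0.97), with a range over alternatives of 7.9e-06 to 0.97. Their median was -0.80 without DSF 4 h replicate 1. Chaperones no longer passed without DSF 8 h replicate 1 (adjusted p = 0.088) and without DSF 4 h replicate 2 (median 0.20, adjusted p = 0.12), with a range over alternatives of 0.0025 to 0.12. The median of photosynthesis genes was -0.13 with quantile normalization, -0.56 with the mean of all probes, -0.45 without DSF 4 h replicate 1, -0.10 without DSF 8 h replicate 1 and -0.11 without DSF 4 h replicate 2. The median of auxin genes was -0.87 with normexp and -0.84 without DSF 4 h replicate 1. The median of morning genes was -0.55 with normexp. The median of evening genes was -1.18 with the mean of all probes. The median of heat shock genes was -0.69 with normexp. Higher genes outnumbered lower ones with quantile normalization (418 and 342), with normexp (370 and 354) and with normexp and quantile normalization (483 and 430). With normexp ALD1 was -1.18, and FT (1.04, adjusted p = 0.218) and ERF71 (-1.08, adjusted p = 0.062) did not pass. CIPK20 was -3.41 with normexp. FT, ERF71 and CIPK20 were thus smaller in size than their bounds.

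Comparing 16 h with 8 h asks how expression moved late in the DSF series. From 8 h to 16 h, photosynthesis and morning clock genes rose as groups and phenylpropanoid and jasmonate genes fell (adjusted p = 0.21 to 0.61 with an estimated correlation). CIPK20 was at least 248-fold higher at 16 h, and PRR9 at least 29.3-fold. BBX28 (5.58 ± 0.37) and LHCB2.2 (5.59 ± 0.39) rose. JMJD5 (-6.41 ± 0.52), CYP81F4 (-5.79 ± 0.50), RVE2 (-5.57 ± 0.33) and COR27 (-5.22 ± 0.25) fell, and CO was at least 17.8-fold lower.

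Morning clock genes rose in 9 of 10, the same count as adjusted over the list alone, with CCA1 (4.84 ± 0.19) and LNK3 (4.11 ± 0.19). Morning genes had a median of 3.03 (camera adjusted p = 1.6e-10, adjusted p = 0.21 with an estimated correlation). Photosynthesis genes rose in 7 of 29, and 9 adjusted over the list alone, with LHCB1.1 (4.01 ± 0.19) and LHCB2.1 (5.20 ± 0.30). Photosynthesis genes had a median of 0.39 (camera adjusted p = 5e-07, adjusted p = 0.61 with an estimated correlation). Phenylpropanoid and flavonoid genes fell in 12 of 22, and 13 fell and 1 rose adjusted over the list alone, with FLS1 (-3.30 ± 0.25) and 4CL3 (-4.12 ± 0.44). Phenylpropanoid genes had a median of -1.92 (camera adjusted p = 3.7e-06, adjusted p = 0.51 with an estimated correlation). Jasmonate genes fell in 6 of 22, and 13 adjusted over the list alone, with VSP1 (-3.30 ± 0.36) and the repressor JAZ7 (AT2G34600, -2.51 ± 0.40). Jasmonate genes had a median of -1.09 (camera adjusted p = 4.8e-07, adjusted p = 0.61 with an estimated correlation). Salicylic acid defence rose in 7 and fell in 2 of 20, 9 and 4 adjusted over the list alone, with PR5 (1.69 ± 0.17), ALD1 (2.46 ± 0.34), ICS1 (1.89 ± 0.29) and FMO1 (1.76 ± 0.30) higher. Salicylic acid genes had a median of 0.64 (camera adjusted p = 0.036, adjusted p = 0.63 with an estimated correlation).

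Chaperones of the endoplasmic reticulum rose in 2 of 11, the same count as adjusted over the list alone, BIP3 (3.02 ± 0.45) and PDIL1-1 (1.15 ± 0.23). Chaperones had a median of 0.56 (camera adjusted p = 0.00028, adjusted p = 0.51 with an estimated correlation). In auxin and growth 3 rose and 1 fell of 13, the same counts as adjusted over the list alone, with IAA19 (1.29 ± 0.24) higher and IAA5 (-0.74 ± 0.17) lower. Auxin genes had a median of 0.79 (camera adjusted p = 0.0016, adjusted p = 0.59 with an estimated correlation). Sugar starvation genes rose in 3 and fell in 1 of 12, 5 and 1 adjusted over the list alone, with ASN1 (3.48 ± 0.51) and TPS11 (2.19 ± 0.25) higher. Starvation genes had a median of 0.60 (camera adjusted p = 0.0084, adjusted p = 0.41 with an estimated correlation). Among other WRKY factors WRKY40 (AT1G80840, -1.80 ± 0.34) and WRKY18 (-1.38 ± 0.27) fell (1 higher and 5 lower adjusted over the list alone). In pattern-triggered immunity CYP81F2 rose (adjusted p = 0.0166) and PUB22 (-1.72 ± 0.30) fell, the same counts as adjusted over the list alone. Median, mean and test differed in sign for ethylene and defensins, camalexin, abscisic acid, touch, wound and cold, and guard cells.

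Higher genes numbered 724 and lower genes 1059 (limma, 1783 past the threshold), with 120 and 135 without DSF 8 h replicates 1 and 2 and 370 without DSF 16 h replicate 2. These were 73 higher and 47 lower, 73 higher and 62 lower, and 182 higher and 188 lower, so the excess of lower genes was not seen without a DSF 8 h array. Salicylic acid genes no longer passed with the replicate block (adjusted p = 0.091), with the mean of all probes (adjusted p = 0.052), without DSF 16 h replicate 1 (adjusted p = 0.13), without methanol replicate 1 (adjusted p = 0.063) and without methanol replicate 2 (adjusted p = 0.054), with a range over alternatives of 0.017 to 0.13. The median of photosynthesis genes was 0.24 with quantile normalization and 0.91 with the mean of all probes. In the authors' value table ASN1 (1.2, adjusted p = 0.282) and 4CL3 (-1.25, adjusted p = 0.159) did not pass, nor did IAA5 with normexp (-0.30, adjusted p = 0.323). CIPK20 was 5.05, PRR9 2.26 and CO -1.71 with normexp on the log2 scale, smaller in size than their bounds.

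Comparing 16 h with 4 h asks for the net change over the DSF series. Over that span, evening clock and heat shock genes fell as groups, and morning clock genes and chaperones of the endoplasmic reticulum rose (adjusted p = 0.21 to 0.43 with an estimated correlation). COR27 (-6.70 ± 0.25), GSTU25 (-5.49 ± 0.50), JMJD5 (-5.36 ± 0.52), ELF4 (-5.25 ± 0.23) and RVE2 (-4.91 ± 0.33) fell. DREB26 (4.06 ± 0.43), LHY (4.04 ± 0.40), BXL1 (3.79 ± 0.45) and CCA1 (3.78 ± 0.19) rose, and the polygalacturonase PGAZAT (AT2G41850) was at least 28.4-fold higher (adjusted p = 0.0493).

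Morning clock genes rose in 8 of 10, and 9 adjusted over the list alone. Morning genes had a median of 2.34 (camera adjusted p = 2.2e-08, adjusted p = 0.21 with an estimated correlation). Evening genes fell in 7 and rose in 1 of 11, 8 and 1 adjusted over the list alone, with BOA (-4.27 ± 0.16) and PRR3 (-3.06 ± 0.19) lower. Evening genes had a median of -1.91 (camera adjusted p = 5.6e-06, adjusted p = 0.21 with an estimated correlation). Chaperones of the endoplasmic reticulum rose in 7 of 11, and 10 adjusted over the list alone, with BIP3 (3.44 ± 0.45), PDIL1-1 (1.43 ± 0.23), the calreticulin CRT1A (AT1G56340, 1.07 ± 0.22) and ERDJ3B (AT3G62600, 0.94 ± 0.20). Chaperones had a median of 0.83 (camera adjusted p = 1.6e-06, adjusted p = 0.43 with an estimated correlation). Heat shock genes fell in 6 of 11, and 8 fell and 1 rose adjusted over the list alone, with HSP90.1 (-2.69 ± 0.20) and HSP70 (-2.34 ± 0.19) lower. Heat shock genes had a median of -1.29 (camera adjusted p = 0.00041, adjusted p = 0.39 with an estimated correlation). Jasmonate genes fell in 7 of 22, and 14 adjusted over the list alone, with VSP1 (-3.69 ± 0.36), VSP2 (-2.13 ± 0.28) and MYC2 (-1.46 ± 0.28). Jasmonate genes had a median of -0.93 (camera adjusted p = 6.4e-05, adjusted p = 0.71 with an estimated correlation).

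Salicylic acid defence rose in 5 of 20, and 7 rose and 2 fell adjusted over the list alone, with PR1 (2.04 ± 0.39), ICS1 (1.32 ± 0.29) and the lipase-like regulator PAD4 (AT3G52430, 0.97 ± 0.19). Salicylic acid genes had a median of 0.55 (camera adjusted p = 0.01, adjusted p = 0.61 with an estimated correlation). Sugar starvation genes rose in 4 and fell in 1 of 12, 6 and 2 adjusted over the list alone, with TPS11 (2.44 ± 0.25) and TPS8 (2.26 ± 0.28) higher and DIN11 (AT3G49620, -3.00 ± 0.50) lower. Starvation genes had a median of 1.17 (camera adjusted p = 0.0094, adjusted p = 0.41 with an estimated correlation). Of 11 beta-oxidation genes ACX4 (1.11 ± 0.17) rose, also adjusted over the list alone. Beta-oxidation genes had a median of 0.40 (camera adjusted p = 0.043, adjusted p = 0.49 with an estimated correlation). In pattern-triggered immunity MPK3 (1.46 ± 0.19), WRKY33 (1.42 ± 0.20) and CYP81F2 (1.98 ± 0.33) rose and PUB22 (-2.52 ± 0.30) fell (5 higher and 3 lower adjusted over the list alone). The defensins PDF1.2b (AT2G26020, -1.97 ± 0.32) and PDF1.2a (-2.32 ± 0.41) fell (4 higher and 4 lower adjusted over the list alone in ethylene and defensins). Median, mean and test differed in sign for pattern-triggered immunity, ethylene and defensins, camalexin, auxin and guard cells.

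There were 1117 genes higher and 1779 lower at 16 h (limma, 2896 past the threshold), with 1032 and 1303 without DSF 4 h replicates 1 and 2, 1516 without either DSF 8 h array and 907 without DSF 16 h replicate 2. Beta-oxidation genes no longer passed with normexp (adjusted p = 0.052), without DSF 4 h replicate 1 (adjusted p = 0.19), without DSF 8 h replicate 1 (adjusted p = 0.059), without DSF 16 h replicate 1 (adjusted p = 0.052), without methanol replicate 1 (adjusted p = 0.061), without DSF 8 h replicate 2 (adjusted p = 0.054), without DSF 16 h replicate 2 (adjusted p = 0.085) and without methanol replicate 2 (adjusted p = 0.052), with a range over alternatives of 0.02 to 0.19. Salicylic acid genes no longer passed without DSF 16 h replicate 1 (adjusted p = 0.11), with a range over alternatives of 0.0029 to 0.11. The median of jasmonate genes was -0.60 without DSF 4 h replicate 2. The median of heat shock genes was -0.72 with normexp. CCA1 was 2.32 in the authors' value table. With normexp LHY was 2.26 and DIN11 -1.98, and PGAZAT did not pass (2.59, smaller than its bound, adjusted p = 0.0708).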

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

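The test of an equal DSF effect at all times was chosen after the result was seen. The 2 tests on clock genes were planned before it. Because the 3 comparisons with methanol share their control, the difference between 2 of them equals the comparison between the 2 DSF times. It holds change with time of day and time after infiltration, so it does not test whether the effect of DSF itself differed. In it, 786 genes and 9 gene lists differed between 8 h and 4 h, and 1783 genes and 8 lists between 16 h and 8 h. Between 16 h and 4 h, 2896 genes and 8 lists differed. With an estimated correlation 0 of these lists passed (adjusted p from 0.21).

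The differences of DSF at 4 h and 8 h from methanol at 16 h may come from time of day. The median absolute log2 fold change of 21 clock genes, such as CCA1 and ELF4, was 2.23 at 4 h and 1.99 at 8 h, at the 100th percentile of 10000 random lists matched on expression in both (highest random value 0.86 and 0.79). Clock genes change with time of day with or without DSF, so sampling at different times made this outcome likely in advance. It does not show how far the differences of the other called genes come from time of day. A DSF effect of equal size at 4, 8 and 16 h was argued against only as the main source of these differences. In the called direction, DSF over methanol at 16 h kept 13.1% of the median change at 4 h and 24.6% of that at 8 h. The genes were picked by their early difference, which lowers these shares. An equal DSF effect beneath changes with time cannot be told apart here and stays open. A DSF response that had passed before 16 h stays open and was not tested, since no methanol arrays of 4 h or 8 h were analysed here.

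For the weak differences between DSF and methanol at 16 h, a small offset in time of day between the arrays could be an explanation. The same 21 clock genes had a median absolute log2 fold change of 0.25, at percentile 47 of matched random lists (random median 0.26). The bootstrap interval of the median, 0.21 to 0.38, ended just under the 95th percentile of the random lists (0.38, or 0.378 against 0.384). This interval was not part of the planned rule and treats the clock genes as independent. The test argues, by a narrow margin, only against an offset that moves clock genes more than other genes. A smaller offset would not be seen by it and stays open. A DSF effect stays open, and the labels do not name any other difference between these groups.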

How the results depend on the processing

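Of the 341 named results past the threshold, each a gene in 1 comparison, 34 of 73 at 4 h and 30 of 77 at 8 h against methanol, 6 of 54 between 8 h and 4 h, 22 of 65 between 16 h and 8 h and 35 of 72 between 16 h and 4 h kept their direction and side of the threshold in every alternative. The call of 158 and 155 of them was lost without DSF 8 h replicates 1 and 2, of 107 without a filter, of 45 in the authors' value table, where 4 more turned direction, and of 13 with normexp. In the order 4 h and 8 h against methanol, 8 h against 4 h, 16 h against 8 h and 16 h against 4 h, testing all probes without a filter (29135 genes) gave 998, 1046, 147, 562 and 1198 genes, and 395 shared between 4 h and 8 h. It moved the median of all genes by -0.140, -0.121, 0.114 and 0.148 at 4 h and 8 h against methanol and at 16 h against 8 h and 4 h. Fitting only the 2 groups compared gave 570, 2096, 415, 1561 and 769 genes in the same order, with the 3 large drops in the comparisons that include DSF 4 h. At 16 h, quantile normalization called 2 genes. An estimated correlation left 0 of 46 list tests and 0 of 4 at 16 h, and fry left 1 at 16 h. Leaving out each array in turn gave 722 to 2241 genes at 4 h, 274 to 2142 at 8 h, 13 to 674 between 8 h and 4 h, 120 to 1617 between 16 h and 8 h, 907 to 2689 between 16 h and 4 h, 182 to 976 shared genes and 1 to 8 lists at 16 h. There a lone array is assumed to vary like the other groups, and the DSF 8 h arrays, with the smallest spread, moved the counts of other comparisons through the pooled spread. In the authors' value table, HSP90.1 at 4 h was -0.75 (3.25 here), ERF6 at 8 h 0.29 (-1.30), and between 8 h and 4 h 4CL3 was -0.01 (2.85) and PRR7 0.37 (-1.59). The cause was not tested. With the replicate number as a block, 0, 2552, 2392, 816, 1913 and 3211 genes passed (16 h first, then in the order above), with 47 list tests, 5 of them at 16 h, and 1130 shared genes. Deviations of arrays with the same number correlated at -0.07 to 0.41, over 0.1 in 3 of 6 pairs of groups. Replicate 1 had the brighter 75th percentile and the lower score on the third principal component in each group. The numbers were taken to pair the arrays only if all 6 correlations were over 0.1, so the fit without the block was used. Of 124 named results past the threshold with several probes, 4 had probes in opposite directions. A slide or scan block was not run, there being 1 of each. Dim signal limits the genes written as at least N-fold.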

Other observations

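All tests in this part were chosen after the data were seen. Families of genes were formed from shared symbol prefixes, 99 families with at least 12 tested genes, and tested with camera over 594 tests. From the prefixes CRK, RPL and RPS, 9 genes were left out whose full names in the reference table are of other families, such as disease resistance genes and calcium-dependent kinase relatives. With an estimated correlation, a test with little power here, 0 passed in any comparison (camera adjusted p = 0.96 for each family call named here). At 16 h, where single genes did not pass, 21 families did with the preset correlation. Receptor-like proteins, cell surface proteins of which some recognise microbes, lay above 0 with DSF in 87.5% of 48 genes (median log2 fold change 0.64, adjusted p = 6.1e-10). Over all genes 0 passed, adjusted over the family alone 11 did, 21 had an unadjusted p under 0.05, and the median was 0.49 to 0.66 under all scalings. Cysteine-rich receptor-like kinases lay above 0 in 93.9% of 33 genes (0.53, adjusted p = 3e-08, scalings 0.49 to 0.53), with 0 past the threshold over all genes, 6 within the family and 14 at an unadjusted p under 0.05, for example CRK39 (AT4G04540, 2.34 ± 0.39, adjusted p = 0.146 over all genes). The ABCC transporters lay above 0 in all 15 genes (0.56, adjusted p = 6.4e-06), with 0 past the threshold over all genes, 3 within the family and 8 at an unadjusted p under 0.05. Ribosomal proteins of the large subunit had a median of -0.55 over 21 genes (adjusted p = 2.6e-05, scalings -0.57 to -0.43) and of the small subunit -0.52 over 20 (adjusted p = 3.5e-06, scalings -0.53 to -0.42), with 0 genes past the threshold over all genes or within either family and 11 and 10 at an unadjusted p under 0.05.

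At 8 h over methanol at 16 h, the SAUR genes, which respond to auxin, had a median of -2.06 over 14 genes, 8 of which fell (adjusted p = 5.9e-05), and B-box factors -1.06 over 16 genes, with 8 lower and 1 higher (adjusted p = 0.00051). Glycosyltransferases of the UGT family had a median of 0.75 over 54 genes at 4 h (0.44 with normexp), with 16 higher and 1 lower (adjusted p = 4.2e-05). The receptor-like proteins and cysteine-rich kinases had medians of -0.04 and 0.10 at 4 h and of 0.20 and -0.21 at 8 h, and did not pass there (adjusted p = 0.74 and 0.89 at 4 h, 0.13 and 0.36 at 8 h).

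The shift above 0 of the 81 receptor-like protein and cysteine-rich kinase genes at 16 h (median 0.56, 35 at an unadjusted p under 0.05) could reflect DSF or a property of the arrays. A single array of 16 h was argued against as the source, since the median was 0.43 and 0.58 without DSF replicates 1 and 2 and 0.51 and 0.55 without methanol replicates 1 and 2. Expression level alone was argued against as well, since 10000 random lists matched on it had a median of -0.03. Their highest value, 0.19, sets no level for chance. The families were picked after their shift was seen, and genes of a random list need not vary together as those of a family may. A difference between the plants or infiltrations of the 2 groups stays open and was not tested, as does an effect of DSF, which is a hypothesis found and tested on the same arrays.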
